A study of Mus musculus with 2 samples.

How the data were processed

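Single-cell 3′ RNA libraries of sorted mouse lung cells were used, 1 Csf2ra-het and 1 Csf2ra-ko. Per the submitters' processing notes, reads were processed with Cell Ranger 7.0.0 against GRCm39. The authors deposited the values as raw UMI counts per gene and barcode, with 500 UMIs or more in each heterozygous and 509 or more in each knockout barcode. The gene annotation, any filter on barcodes and whether intronic reads were counted are not given in the sources used here. The reference at hand was an annotation of GRCm38, so no coordinates were used, and gene order along GRCm38 served to find neighbours of Csf2ra and of the other measured genes. The heterozygous library held 145465471 UMIs in 9261 barcodes and the knockout library 96047209 UMIs in 5347 barcodes. Median mitochondrial shares were 1.56% and 1.90%, and Rn18s held 2.13% and 2.02% of UMIs.

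Gene lists, class markers, comparisons, filters and the rule for named genes were fixed before the data were examined. Cells were kept with at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs, which left 8768 heterozygous (94.7%) and 5053 knockout barcodes (94.5%). Doublets were scored with an own implementation of the Scrublet score in each library. Its automatic threshold marked 355 heterozygous cells (4.05%) and 6 knockout cells (0.119%), which did not work for the knockout library. In its place the highest-scoring cells were removed, as many as a loading rate of 0.8% per 1000 cells gives (7.01% and 4.04%) times the share of cell pairs from different clusters (85.7% and 88.1%). That removed 527 heterozygous (6.01%) and 180 knockout cells (3.56%) and left 8241 and 4873 cells, with medians of 12112 and 13897 UMIs. This departs from the planned automatic calls, which were run as an alternative for the class shares.

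Kept cells of both libraries were log-normalised and clustered together without batch correction. The 2000 most variable genes were used without mitochondrial and ribosomal genes, Rn18s, Xist, Tsix and 4 Y-linked genes, and without the CD301b+ cDC2 and receptor lists. Clustering used 30 principal components, 15 nearest neighbours and Leiden resolution 1, and gave 27 clusters. A cluster took the class with most fixed markers among its 50 leading genes. It stayed unnamed when no class marker was among those 50 genes, which held for clusters 11 and 23. It also stayed unnamed when fewer than 3 markers were found in 25% of its cells or when another class led its 10 leading genes. The same held when proliferation genes led it or when its depth was low and none of its 10 leading genes was a marker. Classes carry the ending -like because markers alone named them. Unnamed cells were 505 heterozygous (6.13%) and 353 knockout cells (7.24%). Some markers also belong to gene lists, such as Itgae and Naaa for cDC1 and C1qa for interstitial macrophages.

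Shares of cells were given with exact Clopper-Pearson intervals and counts with exact Poisson intervals. UMIs were summed over the cells of a class in each library and scaled to CPM by the total UMIs of the class. Ratios were given with the exact conditional interval at the 95% level. A library with 0 UMIs was set to 3 counts for log2 ratios, and a share of 0 cells was given with 3 cells as its upper limit. Shares of cells with a Mgl2 UMI were taken after each cell was thinned to 2000 UMIs, and cells with fewer were left out. A share for Itgae in cDC1-like cells was added after values had been seen.

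Named genes needed 50 UMIs over both libraries in the class, a UMI in 10% of cells of the library with the higher CPM and a CPM ratio of at least 1.5 in either direction. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, predicted and Rik genes, Rn18s, Xist, Tsix and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were left out. Genes were ranked by the bound of the ratio's interval nearest to 1. The first 12 in each direction were named for cDC2-like and cDC1-like cells, and the first 5 for other classes with 200 cells in each library, which were classical and non-classical monocyte-like and NK cell-like cells. From each list the 3 members with the interval farthest from 1 were candidates for naming.

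Each of 20 gene lists was summarised by the median log2 CPM ratio of its members with 50 UMIs over both libraries. The lists were GM-CSF receptor and related receptors, CD301b+ cDC2 genes, STAT5 and GM-CSF response, type 2 priming and costimulation, cDC2A genes, cDC2B and monocyte-like DC genes, CD103+ cDC1 genes, MHC class II presentation, MHC class I presentation, interferon response, cell cycle, cholesterol synthesis, PPARg and lipid handling, survival and apoptosis, DC maturation and migration, inflammatory cytokines and chemokines, early-response and dissociation genes, DC and monocyte precursor genes, interstitial macrophage genes, and integrins and adhesion. Intervals came from 1000 Poisson resamplings of the counts. Percentiles came from 10000 random lists of the same size drawn within windows of 100 genes of neighbouring mean expression. Members at least 1.5-fold higher or lower were counted by size alone. Outside cDC2-like and cDC1-like cells, list medians were followed under the alternatives and printed for lists outside the central 95% of random lists with a counting interval excluding 0. That restriction was set after a first complete run had been seen. Members of the interferon and cell cycle lists in interstitial macrophage-like cells and of the interferon list in pDC-like and mature DC-like cells were added after their medians had been seen. STAT5 medians in the monocyte-like classes and pDC-like cells, and ratios of the named genes within each cluster of a class, were added in the same way.

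No test was run because each genotype has 1 library, and counting intervals leave out the spread between mice. The ratio rule was tested on simulated data, in which 200 genes were changed in Poisson counts drawn from the cDC2-like and cDC1-like sums, with 50 genes per fold. A ratio of at least 1.5 with an interval excluding 1 was found for 52% and 48% of genes changed 1.5-fold and for 98% and 98% of genes changed 2-fold, in cDC2-like and cDC1-like cells. Genes changed 4-fold were found in 98% and 98% and genes changed 8-fold in 100% and 88%. Among unchanged genes 0.654% and 1.09% met the rule. This simulation holds Poisson noise only.

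Alternatives were a looser cell filter (500 UMIs, 250 genes, 20% mitochondrial) and a stricter one (2000 UMIs, 1000 genes, 5%), doublets left in, Leiden resolution 0.5 and 2, all variable genes, classes by marker score, each library clustered on its own, cells not thinned or thinned to 4000 UMIs and 2 UMIs for a positive cell. For sums they were edgeR TMM scaling, DESeq2 median-of-ratios scaling, every cell thinned to 2000 UMIs before summing, no minimum count, a pseudocount of 1 CPM and the median of the other classes subtracted. Scaling shifted log2 ratios by less than 0.1 in each class except ILC2-like cells, where the shift was 0.115 with TMM and 0.108 with median-of-ratios scaling. Added after values had been seen were the Itgae share, the cDC2-like class without its cluster led by early-response genes, shares of cells with at least 4000 UMIs and the automatic doublet threshold. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.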

Results

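Single-cell RNA was measured in sorted mouse lung cells from a Csf2ra-het and a Csf2ra-ko library made with 10X Genomics 3′ chemistry. Csf2ra encodes the ligand-binding chain of the receptor for GM-CSF, a cytokine that signals through STAT5 in myeloid cells. The protocol names lungs of 3 mice that had received alveolar macrophages as neonates, and it leaves open whether they were pooled in each library. Sorting kept live cells with CD45 and CD11c and left out cells with CD3, CD19, Ly6G or SiglecF, so cell shares are shares within this gate. The heterozygous library held 9261 cell barcodes with a median of 11968 UMIs and 3365 genes per barcode. The knockout library held 5347 barcodes with a median of 13539 UMIs and 3541 genes. After filtering and doublet removal, 8241 heterozygous and 4873 knockout cells were kept. With 1 library per genotype, spread between mice was not measurable and no difference was tested, and each interval below is a 95% interval covering counting error only. Ratios are knockout over heterozygous, and CPM is the UMI count of a gene scaled to the total UMIs of its class.

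Csf2ra itself was compared first, as the targeted gene. Csf2ra was at 182 CPM in the heterozygous library as a whole and at 131 CPM in the knockout library. In cDC2-like cells it was at 149 CPM and 86.3 CPM, a ratio of 0.578 (0.533 to 0.628). cDC1-like cells had 149 CPM and 81.9 CPM, a ratio of 0.550 (0.498 to 0.607). Interstitial macrophage-like cells had the ratio 0.502 (0.420 to 0.599), pDC-like cells 0.698 (0.515 to 0.947), classical monocyte-like cells 0.742 (0.708 to 0.778) and non-classical monocyte-like cells 0.810 (0.786 to 0.834). Mature DC-like cells had 159 CPM and 84.3 CPM, a ratio of 0.529 (0.350 to 0.778), or 0.899 with every cell thinned before summing. Alveolar macrophage-like cells had 198 CPM in the heterozygous and 253 CPM in the knockout library, a ratio of 1.28 (0.942 to 1.74) that turned to 0.643 with thinned cells. In this class transferred alveolar macrophages were not told apart from the mice's own cells. NK cell-like cells, which carry little Csf2ra, had 18.3 CPM and 10.9 CPM, a ratio of 0.595 (0.320 to 1.08). It was 1.02 with thinned cells and 0.356 with doublets left in. The deleted part of Csf2ra is not given in the sources used here, so a 3′ tag outside that part would check nothing.

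Csf2rb, which encodes the signalling chain shared with the interleukin-3 and interleukin-5 receptors, was also lower in knockout cells of several classes. Its ratio was 0.702 (0.652 to 0.755) in cDC2-like cells, from 162 to 114 CPM. In cDC1-like cells Csf2rb was at 154 CPM and 110 CPM, a ratio of 0.711 (0.651 to 0.777). Its ratio in interstitial macrophage-like cells was 0.417 (0.324 to 0.532). pDC-like cells had the ratio 0.956 (0.840 to 1.09) and alveolar macrophage-like cells 1.14 (0.895 to 1.45).

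**Figure D1:**
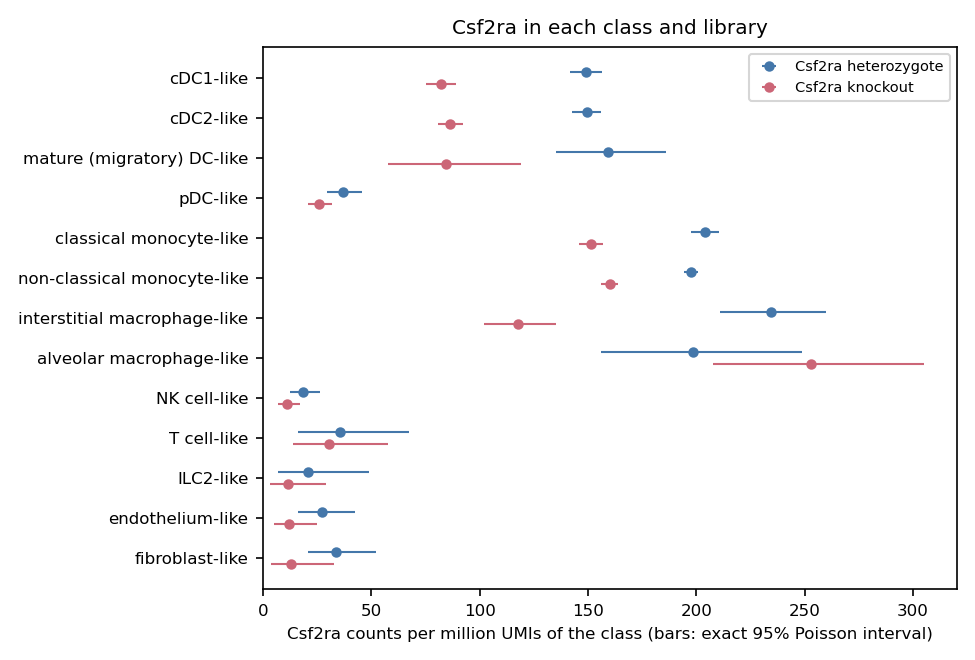
Csf2ra CPM (linear axis) per cell class and genotype, with counting intervals. The value was 149 CPM in heterozygous and 86.3 CPM in knockout cDC2-like cells.

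Class shares addressed whether the sorted lung cells differed in make-up between the genotypes. Knockout cells held a larger share of pDC-like cells, which are dedicated type I interferon producers, at 5.03% against 2.23%, a ratio of 2.25 (1.85 to 2.74). Classical monocyte-like cells were at 14.8% against 10.0%, a ratio of 1.48 (1.34 to 1.64). Non-classical monocyte-like cells, the most numerous class, were at 38.3% against 52.7%, a ratio of 0.727 (0.688 to 0.767). Shares are parts of a whole, so the lower share of this class raises the shares of the other classes. Changes in cell number cannot be read from them. cDC2-like cells, which prime CD4 T cells, were at 12.5% against 10.3%, a ratio of 1.21 (1.09 to 1.34). cDC1-like cells, which cross-present antigen to CD8 T cells, were at 7.20% against 7.90%, a ratio of 0.912 (0.799 to 1.04).

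Mature DC-like cells, marked by Ccr7 and Fscn1, were 0.493% of knockout and 1.55% of heterozygous cells, from 24 and 128 cells. Their ratio was 0.317 (0.196 to 0.493), and it lay between 0 and 0.577 under the other settings. The 0 came from clustering each library on its own, where no knockout cluster took this name. The 24 knockout cells had a median of 11354 UMIs and the 128 heterozygous cells one of 4280 UMIs. Among named dendritic cells, 1814 heterozygous and 1228 knockout cells, cDC1-like cells held 35.9% and 28.6%, a ratio of 0.796 (0.698 to 0.908). cDC2-like cells held 46.9% and 49.5% of them. pDC-like cells held 10.1% and 20%. Mature DC-like cells held 7.06% and 1.95%.

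Several less numerous classes had a larger share in the knockout library. NK cell-like cells were at 4.99% against 2.99%, a ratio of 1.67 (1.39 to 2.00). Interstitial macrophage-like cells were at 3.39% against 2.29%, a ratio of 1.48 (1.19 to 1.83). Basophil or mast cell-like cells were 32 knockout and 13 heterozygous cells, a ratio of shares of 4.16 (2.13 to 8.64). ILC2-like cells, named by 4 markers in a cluster whose leading genes also include the T cell genes Camk4, Itk and Trbc2, were 0.841% against 0.449%, a ratio of 1.87 (1.17 to 3.01). T cell-like cells were 0.698% against 0.340%, with the ratio 2.05 (1.21 to 3.52). Alveolar macrophage-like cells were 0.985% against 0.558%, with the ratio 1.76 (1.15 to 2.70). Endothelium-like cells had the ratio 1.40 (1.08 to 1.83) and fibroblast-like cells 0.859 (0.547 to 1.32). The gate keeps cells with CD45 and CD11c and leaves out CD3+ and SiglecF+ cells. Endothelium-like and fibroblast-like cells were not its target, and how they passed it was not tested. Basophil or mast cell-like, ILC2-like, T cell-like and alveolar macrophage-like cells are few. With classes assigned by marker score the ratio was 1.84 for basophil or mast cell-like, 1.07 for ILC2-like and 1.15 for alveolar macrophage-like cells, and with each library clustered on its own it was 0.886 for T cell-like, 0.992 for endothelium-like and 2.75 for classical monocyte-like cells.

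**Figure D2:**
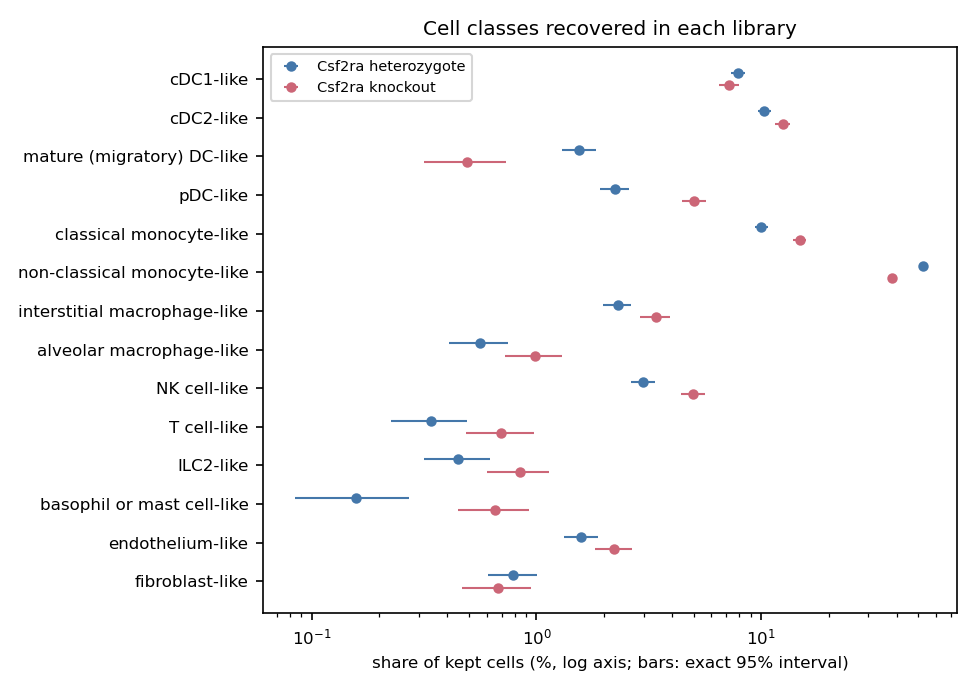
Percent of kept cells per cell class (log axis) in each genotype, with counting intervals. pDC-like cells were at 2.23% and 5.03% and mature DC-like cells at 1.55% and 0.493%.

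CD301b+ cDC2 cells, the population in the title of the series, were measured through Mgl2, the gene for the lectin CD301b. With every cell thinned to 2000 UMIs, 37.7% of heterozygous cDC2-like cells (320 of 848) and 17.0% of knockout ones (103 of 606) carried a Mgl2 UMI. The ratio of these shares was 0.450 (0.357 to 0.564). Mgl2 was at 738 CPM and 237 CPM in the same class, a ratio of 0.321 (0.306 to 0.336). Within each of the clusters that made up the class Mgl2 was also lower in knockout cells, with the ratio 0.784 (0.635 to 0.966) in cluster 6, 0.619 (0.590 to 0.650) in cluster 10 and 0.551 (0.422 to 0.715) in cluster 14. Shares of Mgl2-positive cells within clusters were 4.94% and 4.4% in cluster 6 (ratio 0.891, 0.407 to 1.92), 85.7% and 63.1% in cluster 10 (0.736, 0.569 to 0.944) and 8.93% and 4.43% in cluster 14 (0.496, 0.171 to 1.29). These ratios lay nearer to 1 than that of the class, but the intervals of clusters 6 and 14 included the class ratio. In percentage points the difference in cluster 10 was not smaller than in the class. These clusters held 40.5%, 39.7% and 19.7% of heterozygous and 52.5%, 21.5% and 26.0% of knockout cDC2-like cells.

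Unthinned cDC2-like cells carried a Mgl2 UMI in 46.4% of heterozygous and 26.6% of knockout cells, a ratio of 0.574, at median depths of 14243 and 15660.5 UMIs. Thinning left out 3 heterozygous and 2 knockout cells. Classes that should lack Mgl2 gave its background, which was 0.835% and 0.107% of thinned non-classical monocyte-like cells, 0.729% and 0.277% of classical monocyte-like cells and 1.65% and 0% of NK cell-like cells, where 0 of 237 allows up to 1.27%. Median depths there were 11185 and 14143.5 UMIs for non-classical monocyte-like and 6133 and 6909 UMIs for NK cell-like cells. Interstitial macrophage-like cells, which also carry Mgl2, were positive in 37.0% (64 of 173) and 17.8% (27 of 152), a ratio of 0.480 (0.294 to 0.764). In cDC1-like cells a Mgl2 UMI was found in 10.4% of thinned heterozygous cells (67 of 646) and in 0 of 349 knockout cells, which allows up to 0.860%. Unthinned cDC1-like cells were positive in 24.9% and 1.71%.

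Itgae, the gene for CD103, an integrin chain that binds E-cadherin and marks lung cDC1, was examined in the same way after its values had been seen. Among thinned cDC1-like cells 31.3% of heterozygous (202 of 646) and 3.15% of knockout cells (11 of 349) carried an Itgae UMI, a ratio of 0.101 (0.0495 to 0.184). Itgae was at 251 CPM and 27.2 CPM in the class. Its CPM ratio was 0.194 (0.129 to 0.285) within cluster 7 and 0.176 (0.148 to 0.208) within cluster 8, and the ratios of positive shares were 0.133 (0.0149 to 0.561) and 0.162 (0.0730 to 0.315). Cluster 8 held 58.8% of heterozygous and 32.5% of knockout cDC1-like cells, and cluster 7 held 41.2% and 67.5%. Unthinned, 62.8% and 15.7% of cells were positive, a ratio of 0.249, at median depths of 16335 and 18369 UMIs, and thinning left out 5 heterozygous and 2 knockout cells. The background of Itgae was 0.232% and 0.322% of non-classical monocyte-like, 0.122% and 0.139% of classical monocyte-like and 0.826% and 1.27% of NK cell-like cells.

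**Figure D3:**
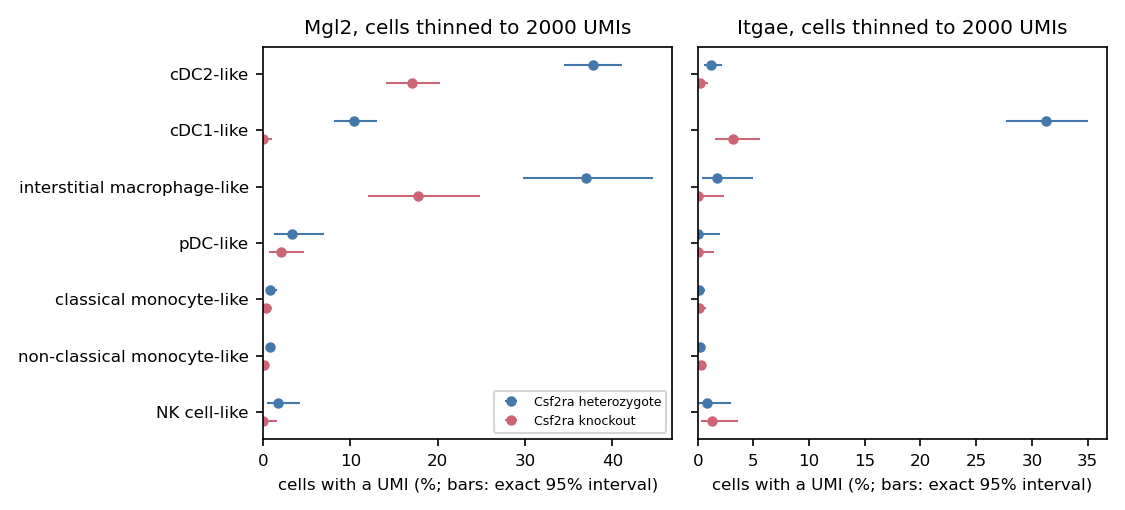
Percent of thinned cells with a Mgl2 or an Itgae UMI per class and genotype, with counting intervals. Mgl2 was found in 37.7% and 17.0% of cDC2-like cells and Itgae in 31.3% and 3.15% of cDC1-like cells.

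Gene expression within cDC2-like cells was compared next, first for the genes picked by size. Ccl17, a chemokine that draws CCR4+ T cells, was at 297 CPM in heterozygous and 5.53 CPM in knockout cells, a ratio of 0.0186 (0.0140 to 0.0243). Flrt3, a leucine-rich repeat adhesion protein, had the ratio 0.00774 (0.00210 to 0.0199), from 669 and 4 UMIs. Cish, a STAT5 target that restrains cytokine receptor signalling, was at 32.0 CPM and 2.87 CPM. Dcstamp, a transmembrane protein of osteoclast and macrophage fusion, was at 122 CPM and 9.63 CPM. Mmp12, the macrophage elastase, was at 96.1 CPM and 11.8 CPM, a ratio of 0.123 (0.10 to 0.149). Bcl2a1a, an anti-apoptotic BCL2 relative, had the ratio 0.166 (0.140 to 0.194). Ear2, a secreted ribonuclease, had the ratio 0.173 (0.148 to 0.201). Clec4n, which encodes the fungal receptor Dectin-2, had the ratio 0.188 (0.149 to 0.234). The other lower genes of this rule were Fgf13, Nav2, Fcrls and Xlr, with ratios from 0.0473 to 0.199. With classes by marker score Dcstamp had the ratio 0.0328, and with thinned cells Fgf13 had 0.0215, Fcrls 0.300 and Flrt3 0.

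Genes picked as higher in knockout cDC2-like cells differed by smaller factors. Dlg2, a synaptic scaffold protein, was at 17.2 CPM and 49.8 CPM, a ratio of 2.90 (2.47 to 3.42). Serpinb10, a serine protease inhibitor, had the ratio 2.59 (2.21 to 3.04). Klf2, a transcription factor of quiescence and trafficking, was at 279 CPM and 480 CPM, a ratio of 1.72 (1.65 to 1.80). Rgl1, an activator of Ral GTPases, had the ratio 1.96 (1.74 to 2.20). Rgcc, a cell cycle regulator, had the ratio 1.77 (1.61 to 1.95). Klf2 was also higher in fibroblast-like cells at 1.70 and Rgcc in NK cell-like cells at 1.59, classes with low Csf2ra. Both were lower in alveolar macrophage-like cells, at 0.395 and 0.809. Sirpb1a, Prkcg and Chil5 had ratios of 1.93, 1.87 and 2.33. Mid1, Rfx2, Mcmdc2 and Itga1 had ratios of 2.45, 2.11, 2.30 and 2.05. With thinned cells the last ratios were 1.40 for Mid1, 1.46 for Rfx2 and 1.49 for Mcmdc2, and Itga1 was at 1.28 with classes by marker score. Of the 24 named cDC2-like genes 17 lay in the same direction in each of the 3 clusters of the class and 9 were at least 1.5-fold apart in each. Within cluster 10, which held most UMIs of the 12 lower genes, Ccl17 had the ratio 0.0371, Flrt3 0.00407 and Mmp12 0.234.

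Gene lists linked to the series title were compared in cDC2-like cells. Their medians were taken over the whole class, whose clusters differed in size between the libraries. Percentiles place a list's median among 10000 random lists of genes with matched mean expression, a description of these libraries. STAT5 and GM-CSF response genes had a median log2 ratio of −0.51 (−0.65 to −0.41), at percentile 0. It was −0.12 with the median of the other classes subtracted. This list shares Csf2rb and Csf2rb2 with the receptor list, and its median here is the value of Csf2rb, given above as a ratio. Of 15 measured members 6 were at least 1.5-fold lower and 0 higher, among them Plet1 with the ratio 0.0311 (0.00632 to 0.0930) and Aldh1a2, a retinoic acid synthesis enzyme, with 0.285 (0.175 to 0.447), or 0.5 with every cell thinned before summing. Type 2 priming and costimulation genes had a median of −0.55 (−0.79 to −0.52), at percentile 0, with 5 of 11 measured members at least 1.5-fold lower and 1 higher. Ccl22, another CCR4 ligand, had the ratio 0.245 (0.210 to 0.284), and Cd274, which encodes PD-L1, had 0.443 (0.361 to 0.540). CD301b+ cDC2 genes, which share Ccl17 with the type 2 list, had a median of −0.13 (−0.32 to 0.20), at percentile 2.52, with 4 of 10 at least 1.5-fold lower and 2 higher, and this median ran from −0.31 to 0.13 under the alternatives. Epcam, a cell adhesion molecule of this list, had the ratio 0.555 (0.457 to 0.670).

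Subset and precursor lists were compared in cDC2-like cells to see which identity genes went with the lower Mgl2. CD103+ cDC1 genes had a median of −0.39 (−0.46 to −0.21), at percentile 0.01, with 4 of 10 at least 1.5-fold lower, among them Naaa, a lysosomal amidase, with the ratio 0.490 (0.447 to 0.536). cDC2B and monocyte-like DC genes had a median of −0.17 (−0.26 to −0.07), at percentile 0.150, with 3 of 14 at least 1.5-fold lower. Fcgr3, an activating Fc receptor, had the ratio 0.523 (0.463 to 0.590), and Cd14, the lipopolysaccharide co-receptor, 0.580 (0.545 to 0.616). cDC2A genes had a median of 0.06 (−0.10 to 0.41), at percentile 66.8, and a mean of −0.03, with Nr4a3 at the ratio 0.464 and Cd7 at 1.5. DC and monocyte precursor genes had a median of 0.25 (0.12 to 0.33), at percentile 100, with 1 of 16 at least 1.5-fold lower and 2 higher. Tcf4, a pDC-lineage transcription factor, had the ratio 1.33 (1.28 to 1.38), and Id2, which opposes it, had 0.421 (0.381 to 0.465). GM-CSF receptor and related receptors had a median of −0.01 (−0.13 to 0.10), at percentile 22.5, with Flt3 at the ratio 1.33 (1.26 to 1.40). The cDC2B median turned to 0.0010 with classes by marker score and to 0.12 with the median of the other classes subtracted.

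Interstitial macrophage genes, markers of a neighbouring class, were also lower in knockout cDC2-like cells, with a median of −0.82 (−0.99 to −0.64) at percentile 0 and 4 of 8 measured members at least 1.5-fold lower. C1qa, a complement component, had the ratio 0.319 (0.280 to 0.363), and Mrc1, the mannose receptor, had 0.404 (0.370 to 0.441). This median was −0.030 with the stricter cell filter, 0.013 at Leiden resolution 2 and 0.43 with all variable genes, where C1qa had the ratio 1.35.

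Function lists in cDC2-like cells covered antigen presentation, cytokines and survival. MHC class II presentation genes had a median of −0.18 (−0.21 to −0.14), at percentile 0.0500, with H2-DMb2 at the ratio 0.419 (0.380 to 0.462) and the invariant chain gene Cd74 at 0.835. MHC class I presentation genes had a median of 0.03 (−0.02 to 0.06), at percentile 50. Interferon response genes had a median of 0.20 (0.12 to 0.27), at percentile 99.8, with 0 of 20 at least 1.5-fold higher and 1 lower. The antiviral gene Mx1 lay just below that fold at 1.5 (1.25 to 1.79), Bst2 had the ratio 1.23 (1.19 to 1.28) and Gbp2 had 0.622 (0.431 to 0.886), or 1.42 with classes by marker score. Inflammatory cytokines and chemokines had a median of −0.40 (−0.53 to −0.33), at percentile 0, with 6 of 15 at least 1.5-fold lower. Cxcl10, Il1a and Il6 had ratios of 0.235, 0.362 and 0.396, and Cxcl10 had 0.454 with classes by marker score. Survival and apoptosis genes had a median of −0.09 (−0.18 to −0.06), at percentile 0.620, with 3 of 14 at least 1.5-fold lower, among them Bcl2a1b with the ratio 0.323 (0.299 to 0.348). DC maturation and migration genes had a median of −0.19 (−0.29 to −0.17), at percentile 0.560, with 3 of 9 at least 1.5-fold lower and 1 higher. The lymph node homing receptor gene Ccr7 had the ratio 0.390 (0.272 to 0.550) and Il4i1 had 1.60 (1.32 to 1.96). PPARg and lipid handling genes had a median of −0.20 (−0.37 to −0.05), at percentile 0.0800, with 3 of 13 at least 1.5-fold lower and 1 higher and the lipase gene Lpl at the ratio 0.182 (0.105 to 0.300), or 0.365 at Leiden resolution 0.5. Early-response and dissociation genes had a median of −0.22 (−0.25 to −0.17), at percentile 0, with Egr2 at the ratio 0.679 and Fosb at 1.48. The inflammatory median turned to 0.066 with the median of the other classes subtracted.

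The remaining lists in cDC2-like cells had medians near 0. Cell cycle genes had a median of −0.02 (−0.12 to 0.14), at percentile 19.1. Cholesterol synthesis genes had a median of 0.01 (−0.11 to 0.08), at percentile 25.7, and a mean of −0.04. Integrins and adhesion genes had a median of 0.05 (−0.02 to 0.12), at percentile 68.5, and a mean of −0.23, with Itgae at the ratio 0.0873 (0.0312 to 0.198) and Cd44 at 1.38 (1.34 to 1.42).

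Expression in cDC1-like cells was compared by the same rules. Ccl17 was at 392 CPM in heterozygous and 8.24 CPM in knockout cells, a ratio of 0.0210 (0.0157 to 0.0274). Plet1, a surface protein of dendritic cells, was at 63.9 CPM and 3.81 CPM. Dst, a cytoskeletal linker protein, was at 191 CPM and 13.1 CPM, a ratio of 0.0689 (0.0549 to 0.0855), or 0.114 with doublets left in. Tnf, the inflammatory cytokine, was at 92.0 CPM and 8.09 CPM, a ratio of 0.0879 (0.0654 to 0.116), or 0.256 with doublets left in. Gadd45b, a stress response gene, had the ratio 0.108 (0.0853 to 0.135), or 0.265 with doublets left in. Cish had the ratio 0.0364 (0.00742 to 0.109), from 136 and 3 UMIs, or 0.151 with doublets left in. Mgl2 had the ratio 0.0230 (0.0115 to 0.0415), or 0.197 with doublets left in. The rest of the lower genes were Bend6, Ccdc149, Bcar3 and Macrod2, with ratios from 0.0519 to 0.0817, and Itgae. Macrod2 was at 0.215 with classes by marker score and 0.0303 with thinned cells, Bend6 at 0.104 with the looser cell filter and Plet1 at 0.0914 with thinned cells.

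Transcription factors were among the genes picked as higher in knockout cDC1-like cells. Id3 had the ratio 2.05, Bcl11a 1.74, Mycl 1.77 and Meis1 2.13. Mid1, a ubiquitin ligase, had the ratio 3.46. Aacs, which activates acetoacetate, had the ratio 2.22, and Trpm2, a calcium channel, had 2.15. Fam185a, Snx24, Adam22 and Stxbp6 had ratios from 1.78 to 2.00. Scgb1a1, the secretory protein of airway club cells, was at 74.8 CPM and 358 CPM, a ratio of 4.79, with a UMI in 16.3% and 14.0% of cells. The Scgb1a1 ratio was 1.19 with classes by marker score and 14.2 with the stricter cell filter. With thinned cells Meis1 was at 1.08, Mycl at 1.36, Adam22 at 2.89 and Mid1 at 8.33, and with doublets left in Bcl11a was at 1.48. Of the 24 named genes 21 lay in the same direction in both clusters and 12 were at least 1.5-fold apart in both. Within cluster 8 Id3 had the ratio 0.124 and Meis1 0.268, and within cluster 7 Scgb1a1 had 0.111, opposite to the class. Tnf had the ratio 0.907 (0.485 to 1.69) and Dst 0.927 (0.427 to 2.00) within cluster 7, where they had few UMIs, and 0.0986 and 0.107 within cluster 8. Ccl17 had the ratio 0.112 within cluster 7 and 0.0360 within cluster 8.

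**Figure D4:**
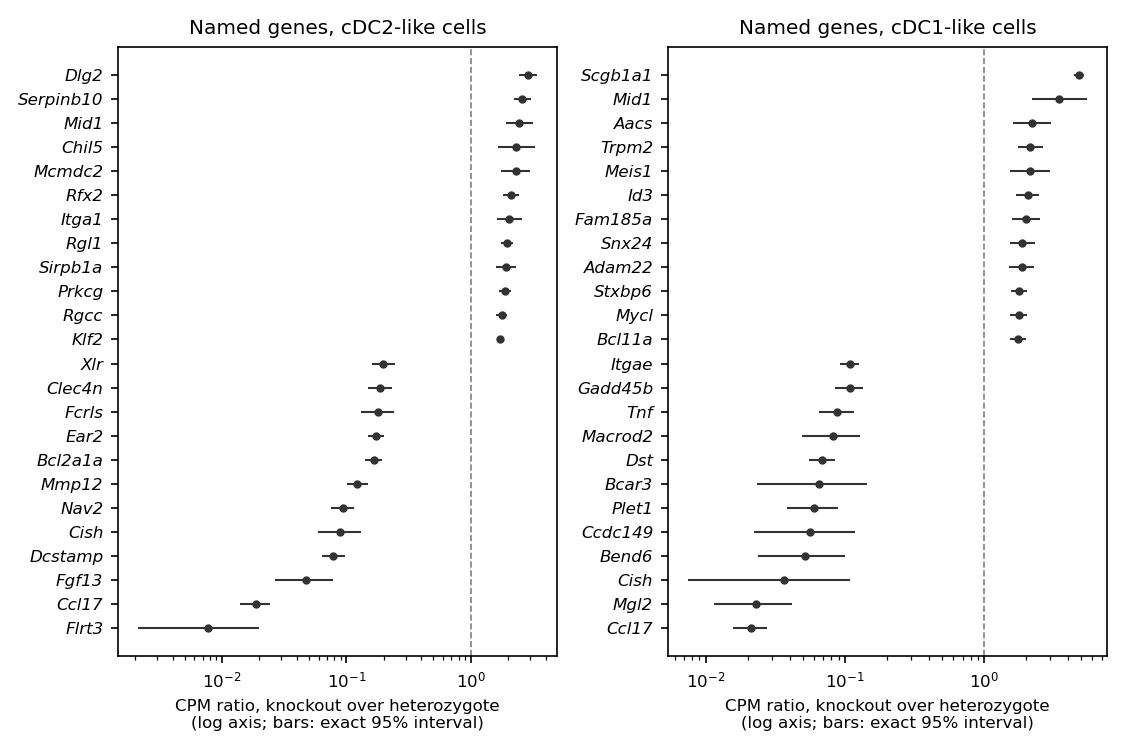
Ratio of CPM, knockout over heterozygous (log axis), of the genes picked by size in cDC2-like and cDC1-like cells, with counting intervals. Ccl17 had ratios of 0.0186 and 0.0210.

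Gene lists linked to the series title were lower in knockout cDC1-like cells taken as a whole. Cluster 8, which held most Ccl17 UMIs, made up 58.8% of heterozygous and 32.5% of knockout cells of the class. List medians were not computed within clusters, so they do not separate cluster sizes from expression. STAT5 and GM-CSF response genes had a median log2 ratio of −1.46 (−1.67 to −1.28), at percentile 0, with 8 of 11 measured members at least 1.5-fold lower and 0 higher. Ccnd2, the gene for a D-type cyclin, had the ratio 0.235 (0.195 to 0.281). Type 2 priming and costimulation genes had a median of −1.08 (−1.35 to −0.95), at percentile 0, with 6 of 9 at least 1.5-fold lower. Ccl22 had the ratio 0.153 (0.130 to 0.178), and the costimulatory receptor gene Cd40 had 0.281 (0.220 to 0.355). CD301b+ cDC2 genes had a median of −0.84 (−1.24 to −0.38), at percentile 0, with 4 of 8 at least 1.5-fold lower and Epcam at the ratio 0.294 (0.258 to 0.334). GM-CSF receptor and related receptors had a median of −0.49 (−0.62 to −0.37), at percentile 0.0600, with Csf2rb2 at the ratio 0.553 (0.417 to 0.725), or 0.289 with every cell thinned before summing, and Csf1r at 0.527 (0.437 to 0.634), or 0.817 with doublets left in. With doublets left in, the STAT5 median was −0.76, and with every cell thinned before summing the CD301b+ cDC2 median was −3.05 and the type 2 median −1.74.

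Survival, maturation and cytokine lists had medians below 0 in cDC1-like cells. Survival and apoptosis genes had a median of −0.63 (−0.78 to −0.53), at percentile 0, with 8 of 14 at least 1.5-fold lower. Bcl2a1b, Bcl2a1a and Bcl2l1, all anti-apoptotic, had ratios of 0.134, 0.159 and 0.268, and Bcl2a1b had 0.265 with doublets left in and 0.0763 with thinned cells. DC maturation and migration genes had a median of −0.98 (−1.25 to −0.87), at percentile 0, with 5 of 8 at least 1.5-fold lower. Icam1, an adhesion ligand for T cells, had the ratio 0.296 (0.262 to 0.335), and Marcksl1 had 0.337 (0.290 to 0.389). Inflammatory cytokines and chemokines had a median of −0.61 (−0.94 to −0.51), at percentile 0, with 8 of 15 at least 1.5-fold lower and 2 higher, or a median of −0.19 with the median of the other classes subtracted. Il12b, a subunit of interleukin-12, had the ratio 0.207 (0.172 to 0.247), or 0.109 with thinned cells, and Cxcl10 had 0.0494 (0.0196 to 0.103), or 0.458 with classes by marker score. Early-response and dissociation genes had a median of −0.53 (−0.55 to −0.42), at percentile 0, with 6 of 18 at least 1.5-fold lower, and Egr1 and Ier2 had ratios of 0.569 and 0.563.

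Subset lists in cDC1-like cells had medians from −0.49 to 0.07. CD103+ cDC1 genes had a median of −0.04 (−0.08 to 0.01), at percentile 16.8, and a mean of −0.50, with 3 of 12 at least 1.5-fold lower. Those members were Itgae, the langerin gene Cd207 with the ratio 0.245 (0.209 to 0.286) and the endocytic receptor gene Ly75 with 0.451 (0.399 to 0.509). cDC2A genes had a median of −0.18 (−0.52 to 0.15), at percentile 16.0, with 4 of 10 members measured, Nr4a3 at the ratio 0.380 and Cd7 at 1.95, or 1.10 with doublets left in. cDC2B and monocyte-like DC genes had a median of −0.17 (−0.37 to −0.14), at percentile 1.11, with 3 of 10 at least 1.5-fold lower and the transcription factor gene Cebpb at the ratio 0.611. DC and monocyte precursor genes had a median of 0.07 (0.02 to 0.13), at percentile 76.9, with Siglech at the ratio 0.513 and Cd34 at 1.91, or 0.327 and 1.01 with every cell thinned before summing. Interstitial macrophage genes had a median of −0.49 (−1.10 to 0.01), at percentile 3.06, with 5 of 14 members measured, 2 at least 1.5-fold lower and 1 higher, and this median was 0.16 with doublets left in.

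Other function lists in cDC1-like cells had medians from −0.19 to 0.06. MHC class II presentation genes had a median of −0.07 (−0.09 to −0.03), at percentile 8.55, with H2-DMa at the ratio 0.809. MHC class I presentation genes had a median of 0.06 (−0.01 to 0.13), at percentile 76.2, with the immunoproteasome gene Psmb8 at the ratio 1.16. Interferon response genes had a median of −0.17 (−0.27 to −0.01), at percentile 2.13, with 3 of 16 at least 1.5-fold lower and Oasl2 at the ratio 0.285 (0.153 to 0.496), or 0.631 with doublets left in and 0.515 with classes by marker score. Cell cycle genes had a median of −0.02 (−0.18 to 0.12), at percentile 36.0, with the proliferation marker Mki67 at the ratio 0.360, or 0.693 at Leiden resolution 0.5, and the replication gene Mcm5 at 1.46. The cell cycle median was 0.45 with doublets left in, 0.44 with the stricter cell filter and 0.24 at Leiden resolution 0.5. Cholesterol synthesis genes had a median of 0.04 (−0.10 to 0.15), at percentile 54.1, with Fdps at the ratio 1.51. PPARg and lipid handling genes had a median of −0.19 (−0.29 to −0.08), at percentile 3.22, with 1 of 10 at least 1.5-fold lower and 1 higher and the fatty acid carrier gene Fabp4 at the ratio 0.265 (0.149 to 0.444), or 0.975 with doublets left in. Integrins and adhesion genes had a median of 0.00 (−0.05 to 0.06), at percentile 38.4, and a mean of −0.28. The interferon median turned to 0.20 with classes by marker score and to 0.035 with every cell thinned before summing, and the MHC class II median was 0.0075 with doublets left in.

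**Figure D5:**
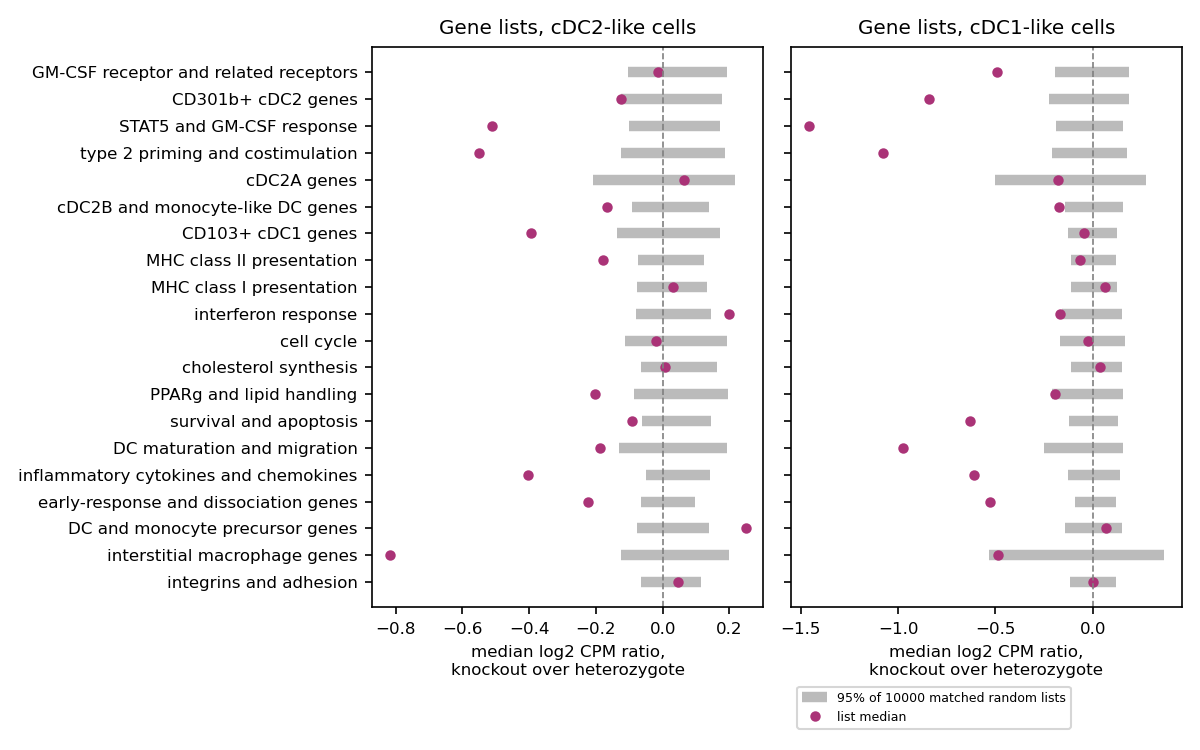
Median log2 ratio of CPM, knockout over heterozygous, of the fixed gene lists in cDC2-like and cDC1-like cells. Lines give the central range of random lists with matched mean expression, not counting intervals. STAT5 and GM-CSF response genes had medians of −0.51 and −1.46.

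Monocyte-like cells were compared because they share the lung tissue and carry Csf2ra. Chil1, a chitinase-like protein, was at 10.9 CPM in heterozygous and 0.0492 CPM in knockout classical monocyte-like cells, from 209 UMIs and 1 UMI, a ratio of 0.00453 (0.000114 to 0.0255). In non-classical monocyte-like cells Chil1 had the ratio 0.00643 (0.00236 to 0.0140), or 0.000921 with doublets left in and 0 with classes by marker score. With the looser cell filter the classical ratio of Chil1 was 0.0215. Capn11, a calpain protease, had ratios of 0.0905 (0.0494 to 0.154) and 0.127 (0.0944 to 0.168) in these classes. The first was 0 with every cell thinned before summing. Slc15a2, a peptide transporter, had ratios of 0.343 and 0.344. Chil3, another chitinase-like protein, was at 756 CPM and 368 CPM in classical monocyte-like cells, and the neutrophil chemokine gene Cxcl2 had the ratio 0.457 (0.412 to 0.508). Il10, an anti-inflammatory cytokine, was at 30 CPM and 3.47 CPM in non-classical monocyte-like cells, a ratio of 0.116 (0.0966 to 0.137), and Gbp7 had 0.331 (0.276 to 0.395). The clusters of the class differed in size between the libraries, with cluster 1 at 26.2% and 42.3%, cluster 2 at 20.7% and 13%, cluster 3 at 18.2% and 9.38% and cluster 0 at 34.9% and 35.3%. Within clusters 0, 1, 2 and 3 Il10 had ratios of 0.129, 0.116, 0.115 and 0.227.

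Rfx2, a transcription factor of ciliated cells, was higher in knockout monocytes of both kinds, with ratios of 1.84 (1.69 to 2.00) in classical and 2.62 (2.48 to 2.77) in non-classical monocyte-like cells. Mid1 had the ratio 5.03 (3.17 to 8.34) and the heat shock gene Hsph1 1.91 (1.70 to 2.15) in classical monocyte-like cells. Ankdd1a had 2.13 there, or 1.39 with all variable genes, and Ccnd1 had 1.87, or 0.915 with classes by marker score. Stxbp6, a regulator of vesicle fusion, had the ratio 2.86 (2.74 to 2.98) in non-classical monocyte-like cells. Fosb, Sgms2 and Ypel2 had ratios of 2.40, 2.37 and 2.12 in the same class, and Sgms2 had 1.18 within its cluster 2. In both monocyte-like classes 10 of 10 named genes lay in the same direction in each cluster and 9 were at least 1.5-fold apart in each. List medians were not computed within clusters.

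Gene lists in non-classical monocyte-like cells included CD103+ cDC1 genes with a median of −0.43 (−0.56 to −0.27) and type 2 priming and costimulation genes with a median of −0.36 (−0.46 to −0.30). Inflammatory cytokines and chemokines had a median of −0.34 (−0.46 to −0.16) there and −0.17 (−0.21 to −0.05) in classical monocyte-like cells. cDC2B and monocyte-like DC genes had a median of −0.18 in the non-classical and −0.13 in the classical class. GM-CSF receptor and related receptors had a median of −0.16 (−0.24 to −0.07) in non-classical monocyte-like cells, which became 0.0064 with the median of the other classes subtracted. In classical monocyte-like cells cholesterol synthesis genes had a median of −0.24 (−0.29 to −0.12), and type 2 priming and costimulation genes had one of −0.10 (−0.15 to −0.04). The type 2 median in classical monocyte-like cells turned to 0.018 with the looser cell filter, and the inflammatory medians turned to 0.070 in the classical and 0.099 in the non-classical class with the median of the other classes subtracted.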

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

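For the lower Mgl2 share the tests of depth and free RNA were chosen after the result was seen and the test on C1q was chosen before. A difference in depth is an unlikely explanation, since with every cell thinned to the same UMIs the ratio of shares was 0.450 (0.357 to 0.564). Free RNA carrying Mgl2 is also unlikely, because the largest difference in the 2 monocyte-like classes and NK cell-like cells was 1.65 percentage points against 20.7 points in cDC2-like cells, although 3 of 65 heterozygous fibroblast-like cells (4.62%) and 0 of 31 knockout ones had a Mgl2 UMI. Macrophage-like cells or doublets counted as cDC2-like are unlikely to account for it, as cDC2-like cells without a C1qa, C1qb or C1qc UMI were Mgl2-positive in 34.7% of 789 heterozygous and 15.8% of 588 knockout cells, a ratio of 0.455 (0.356 to 0.578). Differences between mice or between the runs of both libraries remain open with 1 library per genotype.

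For the Csf2ra UMIs found in the knockout library the tests of free RNA and of cells with an intact gene were chosen after the result was seen. Free RNA is unlikely to account for them, since Csf2ra CPM of knockout NK cell-like cells was 0.133 (0.0806 to 0.208) of that of knockout cDC1-like cells. Cells with an intact gene in the knockout library remain open. Over 11 STAT5 and GM-CSF response genes, 248 knockout cDC1-like cells with a Csf2ra UMI were compared with 103 without one. The median CPM ratio was 0.966, with an interval of 0.758 to 1.60 that is too wide to decide. This test covered cDC1-like cells only. Knockout alveolar macrophage-like cells, at 253 CPM of Csf2ra, were not tested, although the mice had received alveolar macrophages as neonates. Transcripts of the targeted gene that keep their 3′ end could not be tested, as the deleted part is not given.

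For genes shifted the same way in classes with high and with low Csf2ra, the tests of free RNA in the whole set and of passenger segments elsewhere were chosen before the result was seen and the others after. The set held 55 genes, 13 called higher and 42 called lower in knockout cells. Each had a ratio of at least 1.5-fold and an interval excluding 1 in at least 4 classes including a class with low Csf2ra. Shifts the other way in further classes were allowed, as for Lyz2, called lower, at 2.69 in T cell-like cells. Ccl3 and Ccl4, also called lower, had a higher CPM in the knockout library as a whole. How many such genes would arise at random was not counted. Klf2, Rgcc, Fgf13, Nav2, Cd274, Slc15a2 and Fosb, named above, belong to the set. Free RNA remains possible for the 11 genes highest in a monocyte-like class, such as Lyz2 and Csf1r. Their median CPM in the shifted low-Csf2ra classes was 0.0755 (0.0590 to 0.148) of the library's. For shifts in those low-Csf2ra classes free RNA is unlikely for the whole set at 1.58 (0.723 to 3.24). The other 44 genes had 2.57 (1.44 to 4.99). Monocyte-like cells held most UMIs of the heterozygous library, so a split by highest class tends by itself to set these group medians apart. The group medians therefore cannot decide the question, and only that of the whole set was free of the split. Single genes depart from their group, with Cst3 at 0.0807 and Ace at 0.0791 among the 44 and Fam78b at 1.23 among the 11. Shifts of these genes in the other classes were not covered by the test, and free RNA remains open there. Mgp, for example, was at 188 times the library's CPM in fibroblast-like cells. Its ratio was 0.280 in cDC2-like, 0.224 in non-classical monocyte-like and 1.90 in interstitial macrophage-like cells. A passenger segment beside Csf2ra held a share of 0.0364 of the set, Grk5 and Zfp950. An effect at the targeted locus on its nearest genes may account for that part, with flanking strain DNA not separated from it. Both genes were known to be shifted when this test was chosen. Of other measured genes 0.0107% had both nearest measured neighbours shifted. Grk5 met the rule in 8 of 13 measured classes and Zfp950 in 4 of 9. Grk5 had the ratio 1.33 (0.983 to 1.81) in endothelium-like cells and Zfp950 1.42 (1.02 to 1.99) in NK cell-like cells. Passenger segments elsewhere in the genome cannot be told apart from a random spread, as 8 of the genes had another within 20 protein-coding genes against 0 to 12 for random sets.

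The following medians differed in sign or size between cell classes, and those differences were not tested. CD301b+ cDC2 genes had a median log2 ratio of 0.36 in pDC-like, −0.84 in cDC1-like, −0.21 in non-classical monocyte-like and −1.45 in mature DC-like cells, or −0.50 there with the median of the other classes subtracted. MHC class II presentation genes had 0.19 in classical monocyte-like, −0.18 in cDC2-like, −0.15 in non-classical monocyte-like and −1.43 in NK cell-like cells, where it was −0.38 with doublets left in, −0.84 with the looser cell filter and −0.84 with classes by marker score. MHC class I presentation genes had 0.27 in mature DC-like, 0.27 in interstitial macrophage-like, −0.26 in classical monocyte-like and −0.28 in non-classical monocyte-like cells. Interferon response genes had 0.20 in cDC2-like, 0.55 in mature DC-like, 0.52 in pDC-like and 0.97 in interstitial macrophage-like cells. The same interferon list had −0.17 in cDC1-like, −0.11 in classical monocyte-like and −0.30 in non-classical monocyte-like cells. PPARg and lipid handling genes had 0.23 in interstitial macrophage-like, −0.20 in cDC2-like and −0.64 in pDC-like cells. Early-response and dissociation genes had 0.26 in pDC-like, −0.53 in cDC1-like, −0.22 in cDC2-like and −0.38 in mature DC-like cells. DC and monocyte precursor genes had 0.25 in cDC2-like and −0.19 in NK cell-like cells. Among cells without a class, cluster 25 held 18 heterozygous (0.218%) and 30 knockout cells (0.616%), a ratio of shares of 2.82 (1.52 to 5.37).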

How the results depend on the processing

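Each genotype has 1 library, so no setting measures the spread between mice, and the cause of any dependence below was not tested. No paired analysis was possible because each genotype has 1 library. Alternatives without the early-response cluster, with only cells of 4000 or more UMIs, with the automatic doublet threshold and for the Itgae share were added after values had been seen. Thinning leaves few UMIs for genes of low expression, and mature DC-like cells differ in depth between the libraries, so values there rest on few counts. Named genes were followed under both cell filters, doublets left in, both Leiden resolutions, all variable genes, classes by marker score, thinning before summing and both scalings. Of the 24 named genes, all stayed at least 1.5-fold in the same direction under each of these settings except as follows. In cDC2-like cells 23 did so with classes by marker score and 21 with every cell thinned before summing. In cDC1-like cells 23 did so with doublets left in, 23 with classes by marker score and 22 with every cell thinned before summing. With no minimum count the rule named 24 genes in each of both classes, and 24 of 24 were shared. The rule still required a UMI in a set share of cells. In cDC2-like cells, and for lower genes in cDC1-like cells, that share alone needs more UMIs than the minimum count. Agreement there was fixed beforehand and cannot show whether the minimum count matters. Only genes higher in knockout cDC1-like cells could have changed. Among list medians of other classes, 470 of 613 values lay within the counting interval, 123 lay outside it in the same direction or around a value not called, and 20 turned direction. Among single genes, 1590 of 1899 values lay within it, 300 outside it and 9 turned direction. Below are the values that left their counting interval or turned direction for class shares, Csf2ra, the Mgl2 share of cDC2-like cells, the Itgae share of cDC1-like cells and gene lists in cDC2-like and cDC1-like cells. For other lists and single genes only values that turned direction follow. They are given as ratios of knockout over heterozygous for shares and CPM, and as median log2 CPM ratios where a list of genes is named.

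With the looser cell filter, the share ratio of non-classical monocyte-like cells was 0.771. STAT5 genes in cDC1-like cells had −1.12, cDC2A genes 0.18, interferon genes −0.30 and cell cycle genes 0.20. Type 2 genes in cDC2-like cells had −0.52. Type 2 genes in classical monocyte-like cells had 0.018. With the stricter cell filter, the share ratio of mature DC-like cells was 0.577. CD103+ cDC1 genes in cDC1-like cells had −0.086, interferon genes −0.29 and cell cycle genes 0.44. cDC2B genes in cDC2-like cells had −1.1e-06, cell cycle genes −0.14 and interstitial macrophage genes −0.030. Type 2 genes in classical monocyte-like cells had 0.015. cDC2B genes in mature DC-like cells had 0.14 and interstitial macrophage genes 2.21. cDC2B genes in pDC-like cells had 0.37. With doublets left in, the share ratio of non-classical monocyte-like cells was 0.795. Receptor genes in cDC1-like cells had −0.13, STAT5 genes −0.76, type 2 genes −0.93, CD103+ cDC1 genes 0.030, MHC II genes 0.0075 and interferon genes −0.37. Cell cycle genes in cDC1-like cells had 0.45, survival genes −0.43, maturation genes −0.87, cytokine genes −0.41, early-response genes −0.41 and interstitial macrophage genes 0.16. CD103+ cDC1 genes in cDC2-like cells had −0.49, maturation genes −0.46, interstitial macrophage genes −0.31 and integrin genes −0.050. Interstitial macrophage genes in mature DC-like cells had 1.38. MHC II genes in non-classical monocyte-like cells had 0.040. Maturation genes in pDC-like cells had 0.10. CPM ratios were 1.20 for C1qa in cDC1-like cells and 1.39 for C1qc in cDC1-like cells.

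With Leiden resolution 0.5, the share ratio of non-classical monocyte-like cells was 0.790. Receptor genes in cDC1-like cells had −0.68, STAT5 genes −0.86 and cell cycle genes 0.24. Cytokine genes in cDC2-like cells had −0.31 and interstitial macrophage genes −0.52. With Leiden resolution 2, type 2 genes in cDC2-like cells had −0.42, CD103+ cDC1 genes −0.53, MHC II genes −0.13, survival genes −0.037, maturation genes −0.072 and early-response genes −0.11. Precursor genes in cDC2-like cells had 0.36 and interstitial macrophage genes 0.013. With all variable genes, share ratios were 1.30 for classical monocyte-like cells and 0.774 for non-classical monocyte-like cells. Type 2 genes in cDC2-like cells had −0.51, cDC2B genes −0.065 and interstitial macrophage genes 0.43. Type 2 genes in classical monocyte-like cells had 0.028, interferon genes 0.060 and cytokine genes 0.020. CPM ratios were 1.35 for C1qa in cDC2-like cells and 1.22 for C1qb in cDC2-like cells.

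With classes by marker score, share ratios were 0.547 for mature DC-like cells, 1.15 for alveolar macrophage-like cells, 1.07 for ILC2-like cells and 1.84 for basophil or mast cell-like cells. STAT5 genes in cDC1-like cells had −0.74, cDC2B genes −0.56, interferon genes 0.20 and maturation genes −0.55. cDC2B genes in cDC2-like cells had 0.0010, MHC I genes 0.065, interferon genes 0.41, cholesterol genes 0.11, lipid genes −0.033 and maturation genes −0.12. Early-response genes in cDC2-like cells had −0.097 and precursor genes 0.40. MHC II genes in classical monocyte-like cells had −0.12. CPM ratios were 1.75 for Ifit2 in cDC1-like cells, 1.42 for Gbp2 in cDC2-like cells and 0.915 for Ccnd1 in classical monocyte-like cells. With each library clustered on its own, share ratios were 0 for mature DC-like cells, 2.75 for classical monocyte-like cells, 0.898 for non-classical monocyte-like cells, 1.08 for interstitial macrophage-like cells, 0.886 for T cell-like cells and 0.992 for endothelium-like cells. With cells not thinned, ratios were 0.574 for Mgl2-positive cDC2-like cells and 0.249 for Itgae-positive cDC1-like cells.

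With every cell thinned before summing, precursor genes in NK cell-like cells had 0.028. CD301b+ cDC2 genes in cDC1-like cells had −3.05, type 2 genes −1.74, MHC II genes −0.024, interferon genes 0.035, maturation genes −1.31 and cytokine genes −0.38. Integrin genes in cDC1-like cells had −0.067. Receptor genes in cDC2-like cells had −0.30, STAT5 genes −0.37, cDC2B genes −0.28, CD103+ cDC1 genes −0.20, interferon genes 0.083 and cholesterol genes −0.16. Lipid genes in cDC2-like cells had −0.51, survival genes −0.38, maturation genes −0.16 and early-response genes −0.11. Cytokine genes in mature DC-like cells had 0.0088. CPM ratios were 0.643 for Csf2ra in alveolar macrophage-like cells, 1.02 for H2-K1 in cDC1-like cells, 0.642 for Csf2ra in cDC1-like cells, 1.82 for Birc5 in cDC2-like cells, 0.672 for Csf2ra in cDC2-like cells and 0.669 for Csf2ra in classical monocyte-like cells. CPM ratios were 0.899 for Csf2ra in mature DC-like cells and 0.770 for Csf2ra in non-classical monocyte-like cells. With TMM scaling, MHC II genes in cDC2-like cells had −0.22 and early-response genes −0.26. With median-of-ratios scaling, MHC II genes in cDC2-like cells had −0.22 and early-response genes −0.26.

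With no minimum count, STAT5 genes in cDC1-like cells had −1.16, type 2 genes −0.89, cDC2A genes 0.31 and interferon genes −0.34. Maturation genes in cDC2-like cells had −0.64 and interstitial macrophage genes −0.35. With the median of the other classes subtracted, receptor genes in cDC1-like cells had −0.23, type 2 genes −0.65, CD103+ cDC1 genes 0.080, MHC II genes −0.012, interferon genes −0.28 and lipid genes −0.031. Survival genes in cDC1-like cells had −0.52, maturation genes −0.85 and cytokine genes −0.19. Receptor genes in cDC2-like cells had 0.16, STAT5 genes −0.12, type 2 genes −0.44, cDC2B genes 0.12, MHC II genes −0.11 and MHC I genes 0.063. Survival genes in cDC2-like cells had −0.014, maturation genes −0.064, cytokine genes 0.066, early-response genes −0.049 and interstitial macrophage genes −0.45. Type 2 genes in classical monocyte-like cells had 0.21, cDC2B genes 0.0054 and cytokine genes 0.070. Receptor genes in non-classical monocyte-like cells had 0.0064, STAT5 genes 0.18 and cytokine genes 0.099. With the early-response cDC2-like cluster left out, interferon genes in cDC2-like cells had 0.31, maturation genes −0.36, early-response genes −0.31, precursor genes 0.37 and integrin genes 0.12.

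With only cells with 4000 or more UMIs, the share ratio of mature DC-like cells was 0.560. With the automatic doublet threshold, the share ratio of non-classical monocyte-like cells was 0.768.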

Other observations

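Interferon response genes had a median log2 ratio in interstitial macrophage-like cells of 0.97 (0.86 to 1.28), and 15 of 15 measured members were at least 1.5-fold higher. Ifit3, which restrains viral RNA translation, had the ratio 5.97 (2.67 to 15.7) from 7 and 45 UMIs, or 2.84 at Leiden resolution 2, and Irf7, a transcription factor of the interferon response, had 3.62 (2.16 to 6.34), or 1.28 with doublets left in. Cell cycle genes had a median of 0.66 (0.39 to 1.05) in the same class, with Top2a, a DNA topoisomerase, at the ratio 5.47 (2.67 to 12.6) and Mki67 at 2.88 (1.88 to 4.54). Top2a had a UMI in 3.17% of 189 heterozygous and 6.67% of 165 knockout cells of this class, and Ifit3 in 2.65% and 7.88%. The intervals treat UMIs as independent, so they may be too narrow where the same few cells carry several list members. In pDC-like cells interferon response genes had a median of 0.52 (0.31 to 0.68), with 6 of 15 at least 1.5-fold higher and 1 lower, and this median was 0.045 with every cell thinned before summing. Rsad2, the antiviral enzyme viperin, had the ratio 4.04 (2.18 to 8.16) in pDC-like cells, or 1.76 with doublets left in, and Ifitm3, an inhibitor of viral entry, had 0.489 (0.428 to 0.559), or 0.995 with the stricter cell filter. Mature DC-like cells had an interferon median of 0.55 (0.36 to 0.93), with Isg15, a ubiquitin-like modifier, at the ratio 3.67 (2.31 to 5.87), or 6.70 with classes by marker score, from 24 knockout cells.

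STAT5 and GM-CSF response genes outside conventional dendritic cells had a median of −0.45 (−0.63 to −0.17) in interstitial macrophage-like, −0.58 (−0.79 to −0.33) in NK cell-like and −0.63 (−0.99 to −0.40) in mature DC-like cells, where it was −0.021 with every cell thinned before summing. The same list had −0.05 (−0.10 to 0.01) in classical monocyte-like, −0.10 (−0.18 to −0.06) in non-classical monocyte-like and −0.17 (−0.28 to 0.01) in pDC-like cells, at percentiles 8.39, 4.38 and 1.49. With the median of the other classes subtracted it was 0.29, 0.18 and 0.13 in these classes. In NK cell-like cells other myeloid lists were lower too, with medians of −0.48 (−0.63 to −0.31) for cDC2B and monocyte-like DC genes and −0.95 (−1.15 to −0.74) for DC maturation and migration genes. Type 2 priming and costimulation genes had a median of −0.68 (−1.13 to −0.47) in mature DC-like cells, or −1.55 with every cell thinned before summing. Emb, a cell adhesion protein, was at 263 CPM in heterozygous and 587 CPM in knockout NK cell-like cells, a ratio of 2.23 (2.00 to 2.5). Eya1, Sox5, Usp18 and Rpgr had ratios of 2.05, 2.70, 2.64 and 3.85 in NK cell-like cells. With every cell thinned before summing Usp18 had 4.42 and Rpgr 2.21. Slc15a2 had the ratio 0.118 (0.0518 to 0.238) there and Ifitm3 0.285. Gngt2 had 0.303, and its CPM in NK cell-like and other low-Csf2ra classes was 0.0849 of the heterozygous library's. The MHC class II genes Cd74 and H2-Eb1, which NK cells carry little of, had ratios of 0.331 and 0.295, or 0.828 and 0.763 with doublets left in. Inflammatory cytokines and chemokines in pDC-like cells had a median of −1.10 (−1.26 to −0.88), or −0.040 with doublets left in, and cDC2B and monocyte-like DC genes there had −0.88, or 0.37 with the stricter cell filter.

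Further list medians outside the random range were as follows. Interstitial macrophage genes had −2.22 (−3.08 to −1.62) in mature DC-like cells, which turned to 2.21 with the stricter cell filter and 1.38 with doublets left in. In the same class the GM-CSF receptor list had −0.55 (−0.97 to −0.15), cDC2B and monocyte-like DC genes −0.40 (−0.53 to −0.0025), or 0.14 with the stricter cell filter, and inflammatory cytokines and chemokines −0.34 (−0.71 to −0.11), or 0.0088 with every cell thinned before summing. NK cell-like cells had −0.49 (−0.68 to −0.29) for inflammatory cytokines and chemokines and −0.13 (−0.20 to −0.05) for integrins and adhesion. pDC-like cells had −0.22 (−0.35 to −0.10) for survival and apoptosis and −0.39 (−0.63 to −0.17) for DC maturation and migration, which was 0.10 with doublets left in. Cholesterol synthesis genes had −0.37 (−0.66 to −0.15) in interstitial macrophage-like cells.

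Y-linked genes were close to absent in both libraries. Ddx3y had 14 and 8 UMIs, Uty 6 and 2, Kdm5d 3 and 2 and Eif2s3y 0 and 0, of 128253022 heterozygous and 88736208 knockout UMIs. Grk5, a receptor kinase next to Csf2ra in GRCm38 order, was at 518 CPM in the heterozygous and 236 CPM in the knockout library as a whole.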
